A study of Mus musculus with 24 samples.

How the data were processed

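RNA sequencing of mouse lung tumours was analysed in 24 libraries, which the labels place in 8 groups of 3 by histology, location, genotype and virus. Per the labels the material was total RNA, and libraries were made with a standard Illumina protocol. The deposited table holds raw read counts per Ensembl gene, which per the labels the authors made by aligning to mm10 with STAR and counting with HTSeq; versions, the annotation release, strand setting and the treatment of reads with several placements are not given in the sources used here. The values are whole numbers and sum to between 20311958 and 143179902 per library. Even counts made up 55.5% to 67.9% of the nonzero counts, and the near-identical pair Gm12895 and Gm12896 had counts within 2.5% of each other in all 24 libraries (lowest count 273405, tolerance 5%), which reads counted for each copy and reads shared out evenly between copies would both give. How mates were counted is not given in the sources used here, and a count need not be 1 fragment. Genes with such copies, which include pseudogenes, H2 genes and hemoglobin genes, are therefore uncertain, and without strand a gene cannot be told from an overlapping antisense gene. The series description states 24 mice, while the library names hold 17 numbers, 7 of them shared by 2 groups; libraries were treated as independent.

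Gene symbols, gene types and positions were taken by Ensembl ID from GENCODE, the mouse release given with the data (mm10); 54079 of 54232 IDs had a symbol and 153 had none. Genes were kept by the filterByExpr function of edgeR 4.0.16 with a count minimum of 10, which left 27994 genes and 99.98% of the counts. Library sizes were scaled by TMM (factors 0.804 to 1.26). CPM values, which are counts per library size, were computed from the deposited counts and these sizes. EdgeR's quasi-likelihood test with robust dispersion was fitted once to all 24 libraries and 8 groups, with 16 residual degrees of freedom, and 9 comparisons were taken as contrasts; a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The biological coefficient of variation was 95%. Joint tests over the 3 genotypes and over the 3 locations used the same model. Every adjusted p of a single gene is from edgeR unless another tool is named. Computations ran in R 4.3.3.

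Before the data were examined, the comparisons, the main test, the alternatives and the rule for naming genes were written down. Genes named were Fgfr1, Mycl, Rb1 and Trp53 in every comparison, then up to 8 with the largest rise and 8 with the largest fall (5 each for FGFR1 minus Mycl, IL minus junction and CMV minus CGRP) among genes called at 2-fold or more, with at least 5 CPM in the higher group and no overlap between libraries, without predicted, immunoglobulin or pseudogene symbols. To these came up to 4 members of each list described with the smallest adjusted p, and the markers Neurod1, Chga, Calca, Sftpc, Scgb1a1, Krt5, Dusp6, Etv4, Etv5 and Spry4. Some genes that this rule selects are not reported here. Where a group had no count in any library, the fold is a lower bound from a floor of 3 counts per library, which covers counting error only.

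For groups of genes, 32 lists of 7 to 28 measured members, drawn up by hand, were tested in each comparison with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the 288 tests. The preset value makes the test liberal where genes of a list vary together between animals, so the same test with an estimated correlation was run beside it. Of 100 list calls, 1 held with the estimated correlation, that of the neuroendocrine list in AdC minus NE. The fry test, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, called 37. Counts of members that rose or fell are from edgeR over all genes tested, and "adjusted over the list alone" restricts the adjustment to the list. A list median with members at 0 in a group set to their bound is given where it differs from the fitted one.

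Alternatives were DESeq2 1.42.0, limma voom, RLE factors or library totals only in place of TMM, no filter on low counts, a filter at 1 CPM in 3 libraries, only the groups compared in the model, a 2-fold minimum, leaving out each library in turn, the library number as a block, and fry or other settings for the lists. Leaving out the 5 libraries with counts in fewer than 20000 genes and testing only protein coding genes were chosen after seeing the data. So was adding sex, inferred from Xist alone (female over 100 CPM), as a covariate. Ddx3y was at 0 to 1.63 CPM in the libraries taken as female and at 2.62 to 21.1 CPM in those taken as male. The model was tested on simulated counts drawn from the means and sizes of the real libraries with 200 changed genes: for AdC minus NE, with 4-fold changes 44 of 100 genes were recovered and with 16-fold changes 65 of 100, with 1 false call; for FGFR1 minus control these were 33 and 64, with 3 false calls. Splice forms, variants and raw reads were not analysed here.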

Results

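RNA of lung tumours was sequenced in 24 libraries, 3 in each of 8 groups. The tumours arose in mice in which Rb1 and Trp53 were inactivated in the lung by an adenovirus carrying Cre recombinase. Cre was driven by a CMV promoter, by the promoter of the neuroendocrine peptide gene Calca (CGRP) or by that of the alveolar surfactant gene Sftpc (SPC). The labels also give a genotype (control, FGFR1 or Mycl overexpression), a histology (NE or AdC) and, for NE tumours, a location (central, junction or IL, which the labels do not expand). The groups were NE central CGRP control, FGFR1 and Mycl, NE CMV Mycl from the central, junction and IL sites, and AdC FGFR1 from CGRP and from SPC virus. The libraries held between 20311958 and 143179902 counts and had a count in 16991 to 32925 genes. Values below are CPM, read counts per library size with TMM scaling, as mean ± SD of 3 libraries, and the fold changes are on the log2 scale. On the first principal component, which held 27.3% of the variance, the 6 AdC libraries lay between 220 and 264 and the 18 NE libraries between -144 and -19.4. The second, with 12.9%, went with the number of genes with a count (Pearson correlation 0.76 over the 24 libraries).

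The introduced genes were examined first, in every library. Fgfr1 (ENSMUSG00000031565, mm10 chromosome 8, 25513654 to 25575718), the receptor tyrosine kinase whose active form the design names, was at 23.9, 130 and 39.4 CPM in the 3 NE libraries labelled FGFR1 and at 24.9, 22.1 and 22 CPM in the controls. It was at 67, 62.9 and 70.8 CPM in the AdC CGRP libraries and at 189, 183 and 101 CPM in the AdC SPC libraries. Mycl (ENSMUSG00000028654, chromosome 4, 122995652 to 123002485), a transcription factor of the MYC family, averaged 59 CPM in the CGRP libraries labelled Mycl and 690 CPM in the controls. Its level was 57.5, 72.1 and 47.4 CPM in those Mycl libraries, against 293, 1747 and 30.4 CPM in the controls and 75, 81.2 and 148 CPM in the NE libraries labelled FGFR1. In the CMV Mycl groups it was at 34.2, 42.2 and 1190 CPM centrally, 54.5, 47.4 and 58.7 CPM at the junction and 72.2, 48.3 and 60.4 CPM at the IL site. The Mycl level therefore does not check the Mycl labels. Nor does the Fgfr1 level check the label of NE FGFR1 replicate 1, which at 23.9 CPM lay within the range of the controls. The groups are named as labelled throughout. Rb1 (ENSMUSG00000022105, chromosome 14, 73183673 to 73325822) and Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873), which the virus was to inactivate, still had counts, known only as a sum per gene, at 21.7 ± 5.14 and 112 ± 41.2 CPM in the controls. Rb1 was called in AdC minus NE alone of the 9 comparisons (adjusted p of 0.15 and more in the others), and Fgfr1, Mycl and Trp53 in none.

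**Figure D1:**
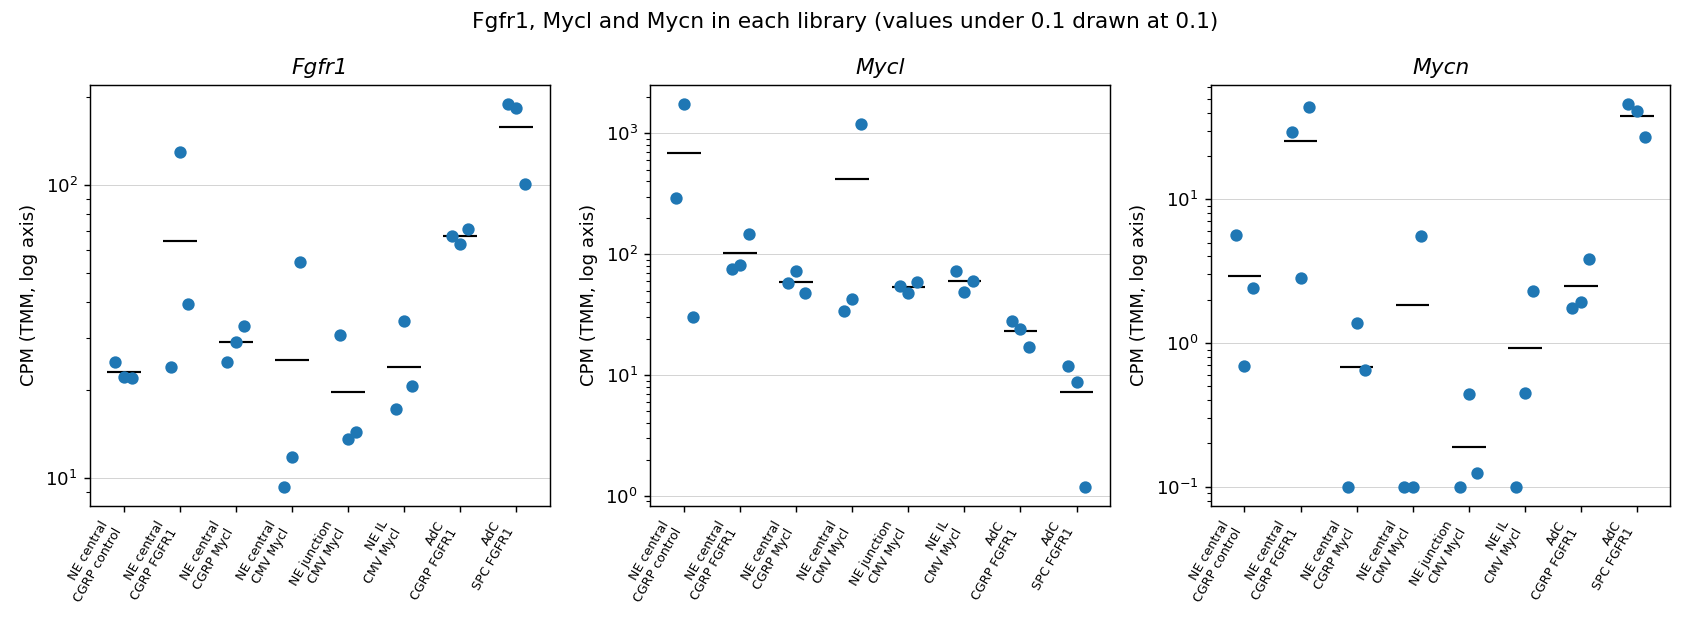
CPM of Fgfr1, Mycl and Mycn on a logarithmic axis in each of the 24 libraries (points), by group, with bars at the group means and values under 0.1 CPM drawn at 0.1. Mycl reaches 1747 CPM in 1 control library and 1190 CPM in 1 central CMV Mycl library, and Mycn, a gene chosen after its values were seen, is at 29.5 and 44 CPM in 2 NE libraries labelled FGFR1.

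Genes beside Mycl were high in the same libraries as Mycl itself; this stretch was chosen after its values were seen. In control replicate 1, control replicate 2 and central CMV Mycl replicate 3, the 10 nearest expressed genes lay on average 0.71, 2.83 and 2.69 above their median over the NE libraries, and in the other 15 NE libraries between -1.96 and 0.25. Mycn (ENSMUSG00000037169, chromosome 12, 12936093 to 12941914), the third of the MYC family, was at 29.5 and 44 CPM in replicates 1 and 3 of the NE libraries labelled FGFR1, where its 10 nearest expressed genes lay 0.6 and 1.73 above their median. It was at most 5.67 CPM in the other NE libraries.

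**Figure D2:**
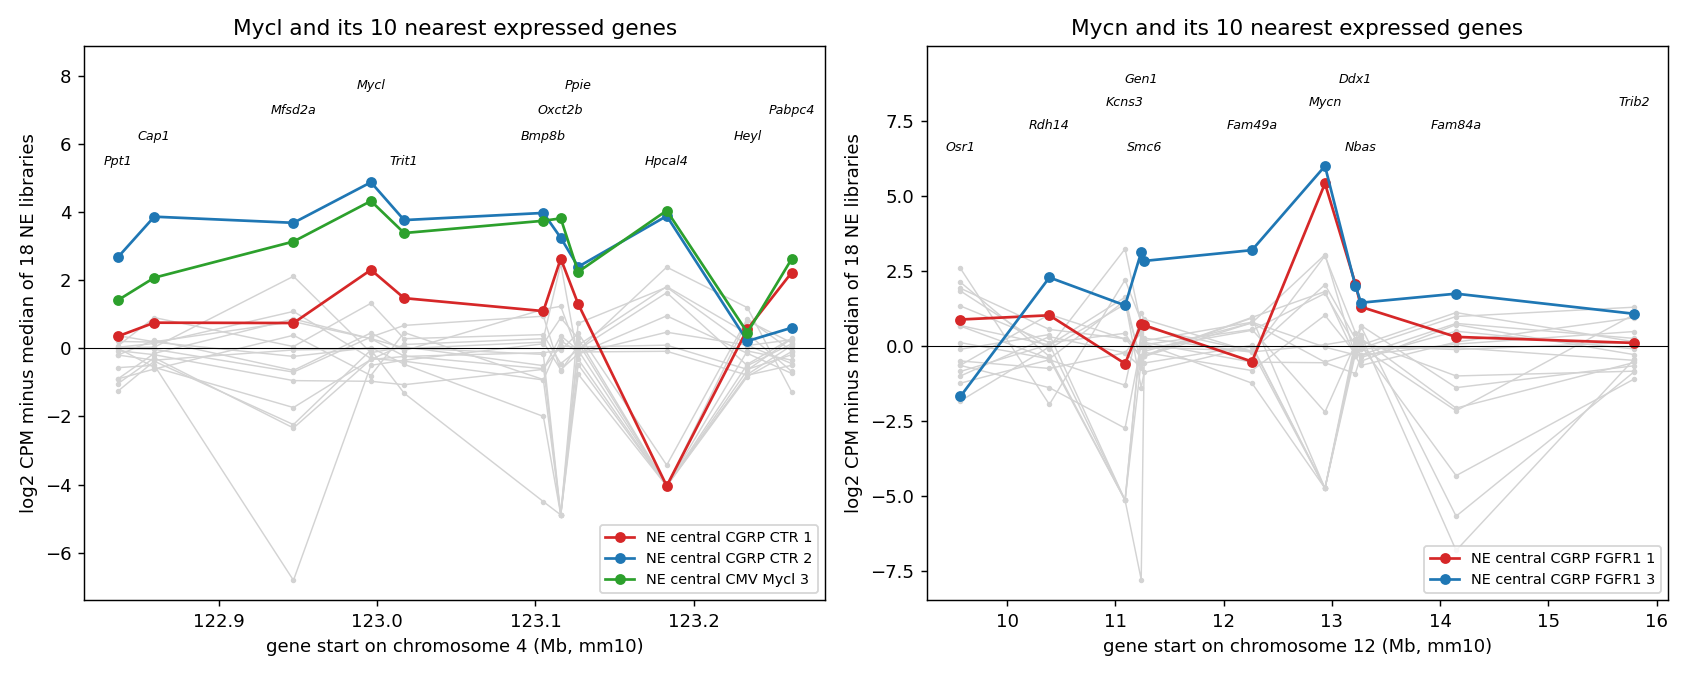
Log2 CPM minus the median of the 18 NE libraries (vertical axis) of Mycl on chromosome 4 and Mycn on chromosome 12 and of the 10 nearest expressed genes of each, by position in megabases. For Mycl the 3 libraries at 4 times its NE median or more are coloured and the other NE libraries grey. For Mycn 5 libraries reach that level, but only FGFR1 replicates 1 and 3 are coloured. Control replicate 1, FGFR1 replicate 2 and central CMV Mycl replicate 3 are grey in that panel. The mean of the 10 neighbours is 2.83 in control replicate 2 and 2.69 in central CMV Mycl replicate 3 for Mycl, and 1.73 in NE FGFR1 replicate 3 for Mycn.

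The central NE tumours from CGRP virus labelled FGFR1 were compared with the controls, which asks what active Fgfr1 adds to the loss of Rb1 and Trp53. No single gene passed the test. The list of feedback and target genes of the ERK pathway, which acts downstream of the receptor, was called up (adjusted p = 0.43 with an estimated correlation). The lists of fibroblast, smooth muscle and MHC class II antigen presentation genes were called down (adjusted p = 0.28, 0.17 and 0.25 with an estimated correlation). Neuroendocrine genes showed no call, as a group or singly.

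Of the 20 ERK genes, 18 had a fold change above 0, and the list was called up by camera (median 0.85, adjusted p = 0.0025), with an adjusted p = 0.43 with an estimated correlation. No member rose over all genes tested and 1 rose adjusted over the list alone. The members were uneven between libraries: Etv4, a transcription factor gene induced by ERK, was at 4.75, 118 and 29.5 CPM, Etv5 at 8.66, 110 and 45.8 CPM, and the phosphatase gene Dusp6 at 19.5, 140 and 27.2 CPM in replicates 1, 2 and 3. The controls were at 5.87 to 15.7, 15.2 to 22.3 and 6.21 to 25.4 CPM. FGFR1 replicate 1 thus lay below every control for Etv4 and Etv5 and within their range for Dusp6. Dusp6 had a fold change of 1.80 and Spry4, a feedback inhibitor gene, one of 1.25, each with an adjusted p of 1 in edgeR. The list of MHC class II genes was called down (median -0.79, adjusted p = 2.2e-06, adjusted p = 0.25 with an estimated correlation). It had 3 members that fell adjusted over the list alone. Fibroblast genes (median -0.78, adjusted p = 1.9e-05, adjusted p = 0.28 with an estimated correlation) had 2 such members, and smooth muscle genes were called down with a median of -0.66 (adjusted p = 0.00038, adjusted p = 0.17 with an estimated correlation). Neuroendocrine genes had a median of 0.16 (camera adjusted p = 0.7). The FGF receptor and ligand list, whose median was 0.14, was not called (adjusted p = 0.93). The introduced gene Fgfr1 itself had a fold change of 1.49 (SE 0.59, adjusted p = 1 in edgeR).

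With edgeR 0 of 27994 genes were called here, and 1080 had an unadjusted p under 0.05; DESeq2 called 93 and limma voom 4. Without control replicate 3 or FGFR1 replicate 1 edgeR called 1 gene, and without FGFR1 replicate 2 it called 2. Camera called 13 of the 32 lists, 3 up and 10 down, of which those of MHC class II, fibroblasts and smooth muscle kept the call without any 1 library. The ERK list lost it without control replicate 2 or FGFR1 replicate 2 (highest adjusted p 0.15).

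The libraries labelled Mycl were compared with the same controls, for the effect of that genotype in central CGRP tumours. The list of interferon response genes was called down and that of ribosome biogenesis genes, many of them targets of MYC factors, up (adjusted p = 0.43 and 0.36 with an estimated correlation). Only 3 single genes passed the test, all lower.

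All 22 interferon response genes had a fold change below 0 (median -0.76, camera adjusted p = 7.4e-05, adjusted p = 0.43 with an estimated correlation). Of 25 ribosome biogenesis genes, 21 lay above 0 (median 0.26, adjusted p = 1.5e-05, adjusted p = 0.36 with an estimated correlation). MHC class I genes were called down (median -0.8, adjusted p = 0.01, adjusted p = 0.69 with an estimated correlation), and 3 of them fell adjusted over the list alone. Cardiac muscle genes were called up (median 1.17, or 1.44 with members at 0 in a group set to their bound, adjusted p = 0.00036, adjusted p = 0.28 with an estimated correlation). For club cell genes the median was -0.23, the mean 0.71 and the test up (adjusted p = 0.026, adjusted p = 0.69 with an estimated correlation). Rasgrf1, a guanine nucleotide exchange factor gene of RAS, was at 0.0108 CPM against 23.3 ± 31.6 CPM (fold change -10.71, SE 1.41, edgeR adjusted p = 0.0027). The other genes called were Tmem125 and Paqr8 (adjusted p = 0.0022 and 0.0027), each with counts of 0 in a group and chosen after their values were seen. Mycl had a fold change of -3.55 (adjusted p = 0.56).

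At an unadjusted p under 0.05 there were 2469 genes. With only the 2 groups in the model 2 genes were called, 1 higher and 1 lower, and none of the 3 was among them (Rasgrf1 adjusted p = 0.95). The number called was 8 without control replicate 1 and 10 without control replicate 2, and Rasgrf1 lost its call without Mycl replicate 1 or 3 (highest adjusted p 0.072). Cardiac muscle genes lost theirs without control replicate 2 (adjusted p = 0.11), MHC class I genes without control replicate 3 or Mycl replicate 1 (highest 0.96), and club cell genes without control replicate 1 or 2 or Mycl replicate 3 (highest 0.55). All 3 Mycl libraries were female by Xist, against 1 of 3 controls. With sex as a covariate the same 3 genes were called, but the list tests were not run with it. The list calls therefore cannot be told apart from this difference. Control replicates 1 and 2 also had high Mycl (293 and 1747 CPM), so a list call cannot be read as an effect of the Mycl label alone.

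Set directly against each other, the FGFR1 and Mycl libraries differed in the lists of interferon response and MHC class I antigen presentation genes, both called higher in FGFR1 (adjusted p = 0.26 and 0.37 with an estimated correlation). The lists of ribosome biogenesis and cardiac muscle genes were called lower (adjusted p = 0.3 and 0.25 with an estimated correlation). Of 62 genes called, 13 were higher and 49 lower.

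All 22 interferon response genes lay above 0, with a median of 1.61 (camera adjusted p = 1e-07, adjusted p = 0.26 with an estimated correlation). None rose over all genes tested and 8 rose adjusted over the list alone, among them Oasl2 (49.1 against 7.74 CPM), Usp18 (35.2 against 4.82 CPM) and Xaf1 (28.2 against 7.42 CPM). Of 14 MHC class I genes 1 rose, and 9 rose adjusted over the list alone (median 1.19, adjusted p = 3.7e-06, adjusted p = 0.37 with an estimated correlation). B2m, the light chain gene of the class I molecule, was at 803 ± 282 against 154 ± 35.8 CPM (fold change 2.38, SE 0.44, edgeR adjusted p = 0.025). The class I heavy chain genes H2-Q4 (193 against 48.2 CPM) and H2-Q7 (518 against 84.5 CPM) have near-identical copies, so their values are uncertain. Ribosome biogenesis genes were called down (median -0.37, adjusted p = 2.2e-06, adjusted p = 0.3 with an estimated correlation), as were cardiac muscle genes (median -1.37, adjusted p = 8.1e-05, adjusted p = 0.25 with an estimated correlation). The ERK genes were all above 0 (20 of 20, median 0.92, adjusted p = 0.029, adjusted p = 0.61 with an estimated correlation), with 3 members that rose adjusted over the list alone. Single genes that rose included Rasgrf1 (10.3 against 0.0108 CPM, adjusted p = 0.0083), Id2, an inhibitor of helix-loop-helix factors (63.2 against 13.7 CPM, adjusted p = 0.025) and Jun (70.8 against 24.7 CPM, adjusted p = 0.029). Those that fell included Ppp1r14b (177 against 535 CPM, adjusted p = 0.0083), Aprt (69.4 against 240 CPM, adjusted p = 0.011), the splicing gene Lsm4 (60.5 against 153 CPM, adjusted p = 0.022) and the ATP synthase gene Atp5g1 (123 against 299 CPM, adjusted p = 0.035). Pseudogenes made up 36 of the 49 that fell, and their reads can be shared with near-identical parent genes.

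All 3 Mycl libraries were female by Xist, against 1 of 3 FGFR1 libraries, and with sex as a covariate 18 genes were called. The FGFR1 libraries had a count in 26644 to 32925 genes and the Mycl libraries in 19489 to 23724. The comparison therefore cannot be told apart from this difference between the libraries. With library totals in place of TMM scaling, 16 genes were higher and 10 lower, and the median over all genes went from 0.14 to 0.33. Each of the 6 libraries decided the count: it was 12, 18 and 8 without FGFR1 replicate 1, 2 and 3, and 16, 6 and 13 without Mycl replicate 1, 2 and 3. Every gene named here lost its call without at least 1 of these libraries (highest adjusted p 0.053 for Rasgrf1, without Mycl replicate 3, and 0.24 for Atp5g1, without FGFR1 replicate 3). The ERK list lost its call without FGFR1 replicate 2, Mycl replicate 1 or Mycl replicate 3 (highest 0.32). Over the 3 genotypes together edgeR called 15 genes, headed by Tmem125, and 2266 genes had an unadjusted p under 0.05. That count was 0 with only the 3 groups in the model and 5 with sex as a covariate.

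AdC and NE tumours of the CGRP virus with FGFR1 were compared for the expression that goes with histology at the same virus and genotype. In the AdC libraries most measured neuroendocrine genes fell, and the genes of alveolar type II cells, which make surfactant, rose. Whether these came from tumour cells or from normal lung taken with them was not tested. The lists of MHC class II, alveolar type I, club cell and macrophage genes were called up, and that of mitotic and DNA replication genes was called down. These calls had an adjusted p = 0.14, 0.25, 0.43, 0.43 and 0.3 with an estimated correlation. Of 27994 genes tested 4008 were called, 1872 higher and 2136 lower in AdC, and 3643 of them changed by at least 2-fold.

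Of 28 neuroendocrine genes 25 fell and none rose (median -7.61, camera adjusted p = 2.8e-36). This is the only list call in any comparison that held with an estimated correlation (adjusted p = 0.006). The secretory granule gene Chga was at 1.38 against 662 ± 433 CPM (adjusted p = 1.9e-06). Calca, whose promoter drove Cre, was at 10.3 against 2484 ± 2049 CPM (adjusted p = 0.00021). The synaptic vesicle genes Rab3b (5.8 against 268 CPM, adjusted p = 3.8e-11) and Syp (2.91 against 292 CPM, adjusted p = 3.1e-10) fell with them. Among the genes with the largest falls were the transcription factor genes Fev, at 0.043 against 204 CPM (adjusted p = 0.00041), and Bsx, which had no count in AdC, was at 51 ± 40.8 CPM in NE and so was at least 1677-fold lower (adjusted p = 0.0029).

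All 21 alveolar type II genes rose (median 7, adjusted p = 2.7e-22, adjusted p = 0.079 with an estimated correlation). The lipid genes of this cell went from 45.6 to 520 ± 145 CPM for Lpcat1 (fold change 3.51, SE 0.29, adjusted p = 9.1e-10), from 32.1 to 336 CPM for the surfactant transporter Abca3 (adjusted p = 1.8e-09) and from 127 to 1196 CPM for Fasn (adjusted p = 6.2e-09). Sftpc, surfactant protein C, was at 2831 ± 2603 against 77.6 CPM (adjusted p = 0.031), a call lost without NE FGFR1 replicate 1 or 3 or AdC replicate 2 (highest 0.13). Of 15 alveolar type I genes 7 rose and 2 fell (median 2.52, adjusted p = 0.00053, adjusted p = 0.25 with an estimated correlation). The water channel Aqp5 rose (236 against 6.47 CPM, adjusted p = 1.3e-06) and Spock2 fell (18.5 against 344 CPM, adjusted p = 1e-04). Club cell genes had 9 of 15 that rose (median 4.73, adjusted p = 0.00034, adjusted p = 0.43 with an estimated correlation). Among them were Cbr2 (7905 against 34.3 CPM, adjusted p = 0.00011) and Cyp2f2 (2217 against 6.61 CPM, adjusted p = 0.0012). Scgb1a1, the main secretory product of club cells, was at 1493 against 197 CPM without a call (adjusted p = 0.21).

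All 7 MHC class II genes rose (median 4, adjusted p = 3.5e-10, adjusted p = 0.14 with an estimated correlation). H2-Aa was at 1693 against 106 CPM (adjusted p = 3.6e-09) and the invariant chain gene Cd74 at 6231 against 347 CPM (adjusted p = 9.6e-08). Macrophage and monocyte genes had 6 of 19 that rose (median 1.79, adjusted p = 3e-04, adjusted p = 0.43 with an estimated correlation). MHC class I genes had 5 of 14 (median 1.26, adjusted p = 0.00018, adjusted p = 0.5 with an estimated correlation). Mitotic and DNA replication genes had 15 of 25 that fell and 20 adjusted over the list alone (median -1.18, adjusted p = 2.7e-08, adjusted p = 0.3 with an estimated correlation). An example is Mcm2, a part of the replicative helicase (74.6 against 260 CPM, adjusted p = 2.4e-06). The Notch pathway list was not called (adjusted p = 0.96), and its members parted. Of them 5 rose, among them the receptor gene Notch1 (49.5 against 5.01 CPM, adjusted p = 6.6e-05), and 4 fell, among them Lfng, Hes6 and Jag2. Yap1, a transcriptional coactivator gene, rose (73 against 6.03 CPM, adjusted p = 6.1e-07). So did Foxj1, the transcription factor of motile cilia (128 against 6.45 CPM, adjusted p = 0.0035), although the ciliated cell list was not called (median 2.3, adjusted p = 0.21). The endothelial list was called up (median 1.42, adjusted p = 0.019, adjusted p = 0.68 with an estimated correlation). It lost that call without NE FGFR1 replicate 1 or 3 or AdC replicate 2 or 3 (highest 0.15). Of its 15 genes 1 rose and Vwf, the von Willebrand factor gene, fell (24.9 against 819 CPM, adjusted p = 8.3e-08).

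Of 20 ERK genes 5 rose and 1 fell; the list median was 0.38 with TMM scaling and -0.1 with library totals only, and camera called it up (adjusted p = 0.046, adjusted p = 0.65 with an estimated correlation). Spry1 rose (148 against 30.8 CPM, adjusted p = 0.00013), Spred3 fell, and Dusp6 and Etv4 had fold changes of 0.30 and 0.09 without a call. Fgfr1 had a fold change of 0.05 (adjusted p = 0.99). These near-equal means rest on NE FGFR1 replicate 2, at 130 CPM for Fgfr1, 140 CPM for Dusp6 and 118 CPM for Etv4. NE FGFR1 replicates 1 and 3 lay below every AdC library for each of these genes. They were at 23.9 and 39.4 CPM for Fgfr1, against 62.9 to 70.8 CPM in AdC. For Dusp6 they were at 19.5 and 27.2 against 67.3 to 83.6 CPM, and for Etv4 at 4.75 and 29.5 against 40.8 to 61 CPM. Rb1 fell (15.4 against 39.9 CPM, adjusted p = 0.036), and lost its call without NE FGFR1 replicate 1 or AdC replicate 1 or 2 (highest adjusted p 0.14). The NE FGFR1 libraries, at 29.7 to 53.2 CPM, lay above every other NE library. The other NE groups averaged 12.2 to 21.7 CPM for Rb1, a range that holds the AdC mean. Among the FGF genes, Fgfr3 rose (adjusted p = 0.00054) and Fgf12, Fgf13 and Fgf14 fell, and the list of receptors and ligands was not called (adjusted p = 0.56). Genes nearly silent in NE and present in AdC included the receptor kinase gene Ros1, at 23.6 ± 8.23 CPM against no count and so at least 1065-fold higher (adjusted p = 0.0021), and Chia1, an acidic chitinase gene, at 246 against 0.104 CPM (adjusted p = 0.00012). Lists not called were those of p53 targets (3 rose, adjusted p = 0.51), RB and E2F-linked cell cycle regulators (1 rose and 4 fell, 0.34), dissociation and heat shock response (2 rose, 0.27), and hypoxia and glycolysis (3 rose and 1 fell, 0.63). The same held for mesenchymal genes (3 rose and 1 fell, 0.55), epithelial junctions and keratins (5 rose and 1 fell, 0.081), and Neurod and Nhlh factors with the POU2F3 and YAP1 subtype genes (1 rose and 1 fell, 0.86).

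With library totals only, 1015 genes were higher and 3623 lower, and the median over all genes went from 0.11 to -0.39. The lists of neuroendocrine, alveolar type II, alveolar type I, club cell, MHC class I, MHC class II, macrophage and mitotic genes kept their calls without any 1 library; the ERK list lost its call without NE FGFR1 replicate 1 or 3 or AdC replicate 2 or 3 (highest adjusted p 0.11).

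**Figure D3:**
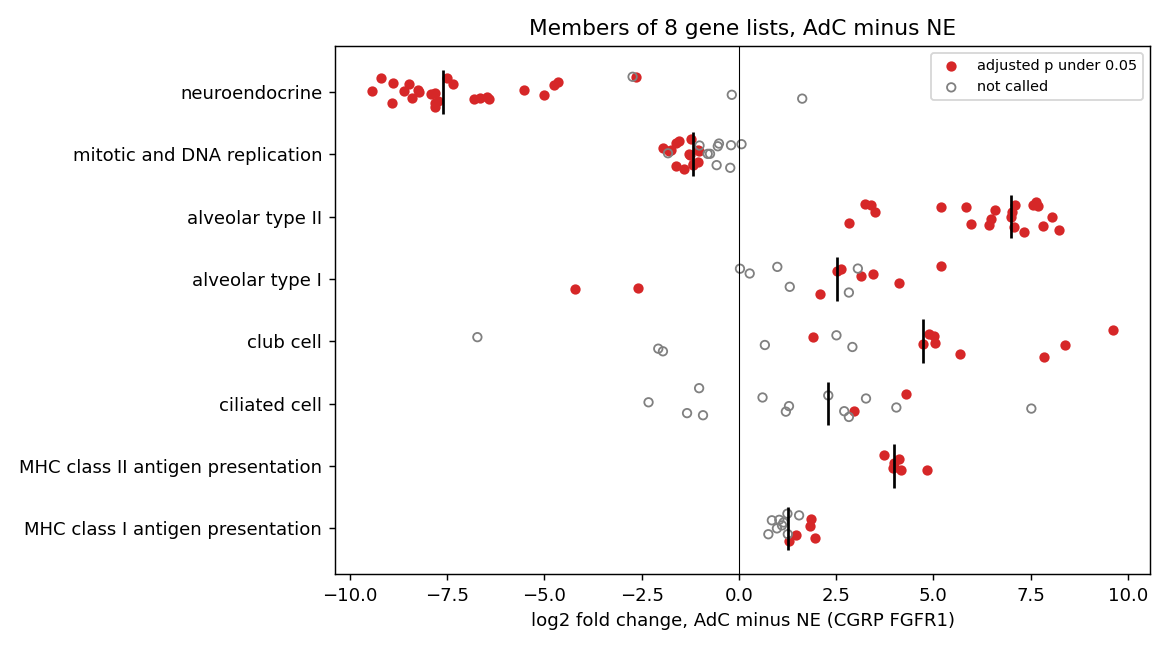
Log2 fold change, AdC minus NE with CGRP virus and FGFR1, of each measured member (points) of 8 gene lists, in red where the edgeR adjusted p is under 0.05 and open grey where not, with a black line at the list median. Neuroendocrine genes have a median of -7.61 and alveolar type II genes one of 7.

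The AdC tumours of both viruses, all labelled FGFR1, were compared to ask whether the cell type in which Cre was expressed left a difference in AdC. The lists of MHC class I, ciliated cell and club cell genes were called lower in tumours from SPC virus (adjusted p = 0.17, 0.12 and 0.42 with an estimated correlation). Those of alveolar type I and of gastric and intestinal genes were called higher (adjusted p = 0.17 and 0.26 with an estimated correlation). In all 360 genes were called, 128 higher and 232 lower in SPC.

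Of 14 MHC class I genes 7 fell, and 12 adjusted over the list alone (median -1.78, camera adjusted p = 2.4e-13, adjusted p = 0.17 with an estimated correlation). H2-K1 was at 711 against 3976 CPM (edgeR adjusted p = 0.00089) and H2-D1 at 531 against 2683 CPM (adjusted p = 0.0024), both with near-identical copies and therefore uncertain. Ciliated cell genes had 3 that fell, and 10 adjusted over the list alone (median -3.6, adjusted p = 3.1e-11, adjusted p = 0.12 with an estimated correlation). Foxj1 was at 0.601 ± 0.366 against 128 ± 144 CPM (fold change -7.74, adjusted p = 0.0013), and Rsph1 and Spag6l fell too. Club cell genes had 2 that fell (median -2.21, adjusted p = 0.00017, adjusted p = 0.42 with an estimated correlation), with Cbr2 at 378 against 7905 CPM (adjusted p = 0.037). Cbr2 kept this call only without CGRP replicate 3, and reached 0.15 without SPC replicate 1. Gastric and intestinal genes had 2 that rose (median 1.61, adjusted p = 0.00011, adjusted p = 0.26 with an estimated correlation). These were Gkn2, a gastrokine (28.5 against 0.028 CPM, adjusted p = 0.0086), and Hnf4a, a transcription factor of gut epithelium (42.6 against 0.33 CPM, adjusted p = 0.02). Alveolar type I genes had 1 that rose, Akap5 (170 against 27.5 CPM, adjusted p = 0.0086), and 5 adjusted over the list alone (median 0.88, adjusted p = 4.1e-05, adjusted p = 0.17 with an estimated correlation). Interferon response genes were called down with 3 that fell adjusted over the list alone (median -1.23, adjusted p = 0.00052, adjusted p = 0.5 with an estimated correlation). B and plasma cell genes were called down as well (3 fell, median -1.61, adjusted p = 0.0011, adjusted p = 0.26 with an estimated correlation). So were p53 targets (median -0.55, adjusted p = 0.019, adjusted p = 0.26 with an estimated correlation), T and NK cell genes (median -1.71, adjusted p = 0.031, adjusted p = 0.59 with an estimated correlation) and macrophage genes (median -0.83, adjusted p = 0.039, adjusted p = 0.71 with an estimated correlation). Each of these 3 lists lost the call without CGRP replicate 3, SPC replicate 1 or SPC replicate 2 (highest adjusted p = 0.11, 0.44 and 0.44).

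The alveolar type II list was not called (adjusted p = 0.98), and Sftpc was at 10284 ± 784 against 2831 ± 2603 CPM (adjusted p = 0.76), while Lyz2 fell (1360 against 9023 CPM, adjusted p = 0.021). The neuroendocrine list was not called either (adjusted p = 0.47), although Ddc, an enzyme of amine synthesis, rose (28.1 against 1.26 CPM, adjusted p = 0.0075). Other single genes included the claudin gene Cldn6 (96.9 against 0.858 CPM, adjusted p = 0.00059), the homeobox gene Lhx2 (0.199 against 27.3 CPM, adjusted p = 0.00011) and the CDK inhibitor gene Cdkn2c (7.66 against 37.9 CPM, adjusted p = 0.0086). Fgfr1 was at 158 ± 49.1 against 66.9 ± 3.95 CPM (fold change 1.24, adjusted p = 0.46).

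The count was 216 without CGRP replicate 1, 219 without CGRP replicate 3, and 178, 140 and 197 without SPC replicate 1, 2 and 3. SPC replicate 3 had a count in 19836 genes. Without all libraries with counts in fewer than 20000 genes, 269 genes were called, 183 of them among the 360. Foxj1, Rsph1, H2-K1, H2-D1, Ddc, Cldn6, Lhx2 and Cdkn2c kept their calls without any 1 library. Gkn2 lost its call without SPC replicate 1 or 3 (highest adjusted p 0.067), Lyz2 without SPC replicate 1 or 2 (0.13), Akap5 without CGRP replicate 1 (0.054), Hnf4a without any CGRP library or SPC replicate 3 (0.12) and Spag6l without CGRP replicate 2 or any SPC library (0.12).

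NE tumours of the CMV virus labelled Mycl were compared between sites, first the junction against the central site. The lists of alveolar type I, alveolar type II, club cell, endothelial and MHC class II genes were called higher at the junction (adjusted p = 0.17, 0.18, 0.18, 0.28 and 0.25 with an estimated correlation). Those of mitotic and of hypoxia and glycolysis genes were called lower (adjusted p = 0.43 and 0.53 with an estimated correlation). Neuroendocrine genes as a list showed no call (adjusted p = 0.84). Of 106 genes called, 90 were higher and 16 lower at the junction.

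Alveolar type II genes had 12 of 21 that rose adjusted over the list alone and none over all genes (median 2.88, camera adjusted p = 3.1e-11, adjusted p = 0.18 with an estimated correlation). Club cell genes likewise had 12 of 15 (median 4.11, or 3.67 with members at 0 in a group set to their bound, adjusted p = 2.5e-09, adjusted p = 0.18 with an estimated correlation). Scgb1a1 was at 7887 ± 4058 against 207 ± 184 CPM (edgeR adjusted p = 0.19) and Sftpc at 793 ± 246 against 42.9 ± 11.3 CPM (adjusted p = 0.26), both without overlap between the libraries, which chance gives in 10% of genes. Alveolar type I genes had 3 that rose, Emp2, Gprc5a and Aqp5 (median 1.65, adjusted p = 3.4e-05, adjusted p = 0.17 with an estimated correlation). MHC class II genes had 3 that rose (median 1.63, adjusted p = 1.6e-06, adjusted p = 0.25 with an estimated correlation). Cd74 was at 865 against 241 CPM (adjusted p = 0.034). Endothelial genes had 8 that rose adjusted over the list alone (median 1.48, adjusted p = 1.8e-06, adjusted p = 0.28 with an estimated correlation). T and NK cell genes had 1 that rose over all genes, Cd3e, with no count centrally and so at least 9.14-fold higher (median 3.26, or 2.87 at the bound, adjusted p = 0.004, adjusted p = 0.43 with an estimated correlation). Mitotic genes were called down (median -0.45, adjusted p = 4.5e-06, adjusted p = 0.43 with an estimated correlation), with 7 that fell adjusted over the list alone. The same held for hypoxia and glycolysis genes (median -0.74, adjusted p = 7.2e-05, adjusted p = 0.53 with an estimated correlation). The neuroendocrine gene Uchl1 fell (349 against 1207 CPM, adjusted p = 0.0091). Genes higher at the junction included Yap1 (14 against 2.23 CPM, adjusted p = 0.0036), the Notch ligand gene Jag1 (fold change 2.87, adjusted p = 0.0038), the cytokine receptor gene Il18r1 (38 against 0.489 CPM, adjusted p = 0.013) and Tmem125 (5.19 against 0.013 CPM, adjusted p = 0.00055). The protease inhibitor gene Serpine2 was lower (33 against 271 CPM, adjusted p = 0.0073).

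The count was 34, 52 and 191 without junction replicate 1, 2 and 3, and 279 without central replicate 3. Central replicates 1 and 2 and junction replicate 2 had counts in fewer than 20000 genes, and without the libraries of that kind, which leaves 1 central library, 16 genes were higher and 22 lower. Yap1, Jag1, Il18r1, Tmem125 and Serpine2 kept their calls without any 1 library. Without junction replicate 1 the adjusted p was 0.071 for Emp2, 0.06 for Gprc5a, 0.074 for Uchl1, which also lost its call without junction replicate 2, and 0.16 for Aqp5, which kept its call only without junction or central replicate 3. Cd74 and Cd3e kept theirs only without junction replicate 3 (highest 0.19 and 0.1).

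**Figure D4:**
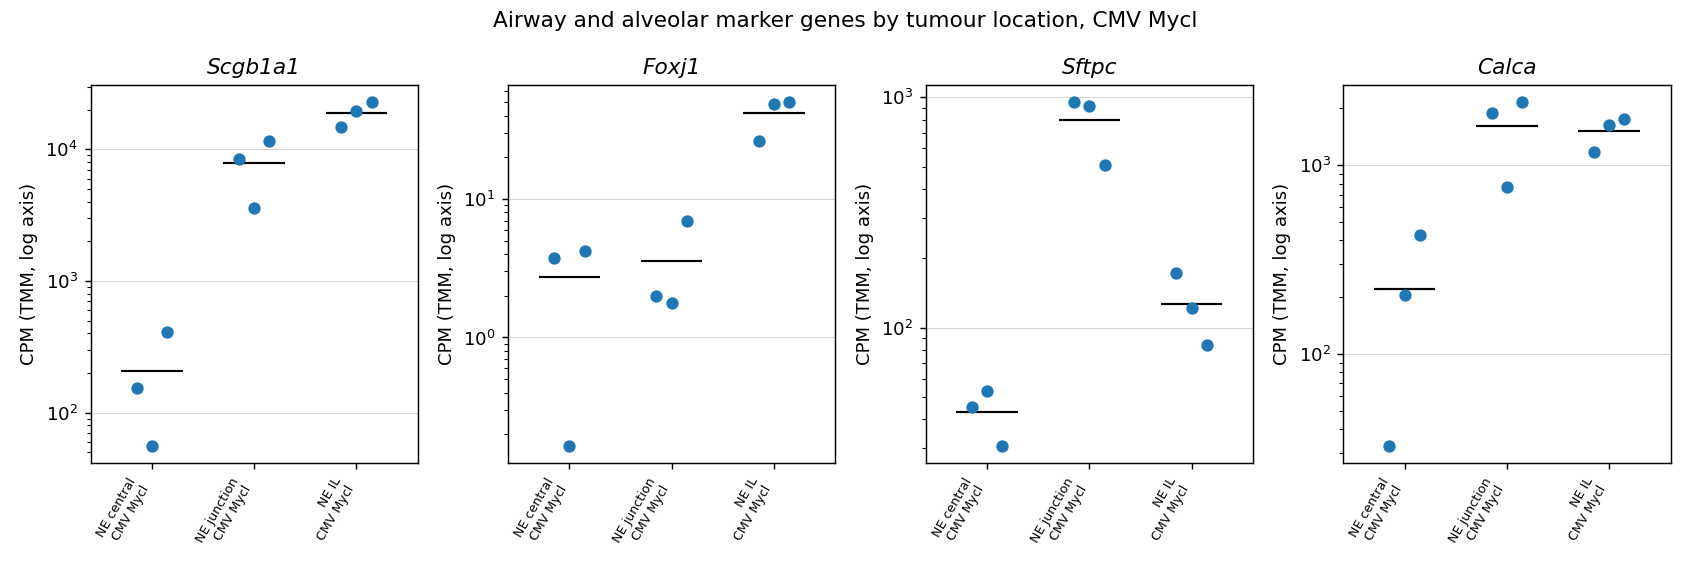
CPM on a logarithmic axis of Scgb1a1 (club cells), Foxj1 (ciliated cells), Sftpc (alveolar type II cells) and Calca (neuroendocrine cells) in each NE CMV Mycl library (points) at the central, junction and IL sites, with bars at the group means. Scgb1a1 averages 207 CPM centrally, 7887 CPM at the junction and 19043 CPM at the IL site, none of which passed the single-gene test.

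The IL site was also set against the central one. The list of club cell genes had the strongest call (adjusted p = 0.079 with an estimated correlation). Those of ciliated cell, smooth muscle, B and plasma cell and interferon response genes were called higher at the IL site as well, and that of hypoxia and glycolysis genes lower (adjusted p = 0.25, 0.17, 0.14, 0.25 and 0.45 with an estimated correlation). All 21 genes called were higher at the IL site.

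Of 15 club cell genes 14 rose adjusted over the list alone and none over all genes (median 5.03, camera adjusted p = 1.9e-17, adjusted p = 0.079 with an estimated correlation). Scgb1a1 was at 19043 ± 4041 against 207 ± 184 CPM (edgeR adjusted p = 0.19). Ciliated cell genes had 4 that rose adjusted over the list alone (median 1.66, adjusted p = 3.6e-06, adjusted p = 0.25 with an estimated correlation); Foxj1 was at 41.6 against 2.72 CPM (adjusted p = 0.15). B and plasma cell genes had 6 such members (median 2.12, adjusted p = 1.3e-06, adjusted p = 0.14 with an estimated correlation). Interferon response genes had 4 (median 1.48, adjusted p = 4.9e-08, adjusted p = 0.25 with an estimated correlation) and smooth muscle genes 4 (median 1.1, adjusted p = 0.00064, adjusted p = 0.17 with an estimated correlation). Hypoxia and glycolysis genes were called down (median -0.68, adjusted p = 5.1e-06, adjusted p = 0.45 with an estimated correlation). Also called up were MHC class II genes (median 1.32, adjusted p = 8.1e-05, adjusted p = 0.31 with an estimated correlation), alveolar type II genes (median 1.55, adjusted p = 0.00043, adjusted p = 0.5 with an estimated correlation) and gastric and intestinal genes (median 2.88, or 2.73 at the bound, adjusted p = 0.00069, adjusted p = 0.32 with an estimated correlation). T and NK cell genes were called up too (median 3.78, or 2.46 with members at 0 in a group set to their bound, adjusted p = 0.0036, adjusted p = 0.43 with an estimated correlation), and these 4 lists kept their calls without any 1 library. MHC class I genes were called up (median 0.89, adjusted p = 1.6e-06, adjusted p = 0.34 with an estimated correlation) and ribosome biogenesis genes down (median -0.23, adjusted p = 0.0069, adjusted p = 0.61 with an estimated correlation). They lost their calls without central replicate 3 (adjusted p = 0.05) and central replicate 1 (0.33). Neutrophil genes were called up (median 3.52, or 3.25 at the bound, adjusted p = 0.028, adjusted p = 0.63 with an estimated correlation), and so were basal and squamous genes (median 1.93, or 1.29 at the bound, adjusted p = 0.035, adjusted p = 0.26 with an estimated correlation). Among the single genes that rose, C3 was at 49.4 ± 5.07 against 2.66 ± 1.4 CPM (fold change 4.19, adjusted p = 6e-04). Ceruloplasmin, Cp, was at 237 against 11.9 CPM (adjusted p = 0.0041), transferrin, Trf, at 135 against 7.42 CPM (adjusted p = 0.011), and Pigr, the carrier of IgA across epithelium, at 57.7 against 1.92 CPM (adjusted p = 0.036). Yap1 rose here too (fold change 2.71, adjusted p = 0.0041).

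The count was 185 without central replicate 3, 8 without IL replicate 2 and 7 without IL replicate 3, and without all libraries with counts in fewer than 20000 genes, which leaves 1 central library, it was 3, all lower and none of them among the 21. C3, Cp and Yap1 kept their calls without any 1 library, Trf lost its call without central replicate 1 or IL replicate 3 (highest adjusted p 0.067) and Pigr without central replicate 2 or IL replicate 2 or 3 (highest 0.15). The neutrophil list lost its call without central replicate 2 or 3 or IL replicate 2 (highest 0.34), and the basal list without central replicate 3 or IL replicate 2 or 3 (highest 0.23). All 3 IL libraries were male by Xist, against 1 of 3 central libraries, and with sex as a covariate 60 genes were called.

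Between the IL site and the junction no gene was called. The lists of ciliated cell and smooth muscle genes were called higher at the IL site (adjusted p = 0.14 and 0.064 with an estimated correlation). Those of endothelial, alveolar type I and alveolar type II genes were called lower (adjusted p = 0.19, 0.14 and 0.37 with an estimated correlation). Also called by camera, though not with an estimated correlation, were the mitotic and the club cell lists. The mitotic list kept its call without any 1 library, and the club cell list lost it without junction replicate 3 (camera adjusted p = 0.075). Club cell genes had a mean log2 CPM of 6.51 to 7.27 at the IL site and 4.31 to 5.52 at the junction.

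All 15 ciliated cell genes lay above 0 (median 1.84, camera adjusted p = 1.8e-09, adjusted p = 0.14 with an estimated correlation), and 1 rose adjusted over the list alone. Smooth muscle genes had 5 such members (median 1.79, adjusted p = 2e-07, adjusted p = 0.064 with an estimated correlation). Endothelial genes had 4 that fell adjusted over the list alone (median -1.06, adjusted p = 2.4e-09, adjusted p = 0.19 with an estimated correlation). Erythrocyte genes had 2 (median -1.37, adjusted p = 0.0012, adjusted p = 0.28 with an estimated correlation). Alveolar type I genes (median -0.84, adjusted p = 5.8e-06, adjusted p = 0.14 with an estimated correlation) and alveolar type II genes (median -0.81, adjusted p = 1.3e-05, adjusted p = 0.37 with an estimated correlation) were called lower, with Sftpc at 126 against 793 CPM (edgeR adjusted p = 0.8). EdgeR called 0 genes, 1654 had an unadjusted p under 0.05, DESeq2 called 242 and limma voom 15. Without junction replicate 3 edgeR called 14. Over the 3 sites together edgeR called 43 genes, headed by Tmem125, C3 and Cyp4v3, and 3199 had an unadjusted p under 0.05.

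Lastly, central NE tumours labelled Mycl were compared between CMV and CGRP virus. The lists of B and plasma cell and of T and NK cell genes were called lower and that of epithelial junction and keratin genes higher with CMV virus (adjusted p = 0.17, 0.28 and 0.17 with an estimated correlation). Of 6 genes called, 3 were higher and 3 lower. CMV replicates 1 and 2 and CGRP replicate 2 had counts in fewer than 20000 genes, and without the libraries of that kind, which leaves 1 CMV library, 10 genes were higher and 1 lower, with 1 of the 6 among them.

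B and plasma cell genes had 3 that fell adjusted over the list alone (median -1.01, or -1.63 with members at 0 in a group set to their bound, camera adjusted p = 3e-05, adjusted p = 0.17 with an estimated correlation). T and NK cell genes had 4 (median -2.9, or -2.74 at the bound, adjusted p = 0.00011, adjusted p = 0.28 with an estimated correlation). Of 17 epithelial junction and keratin genes, 16 lay above 0 (median 0.55, adjusted p = 0.00053, adjusted p = 0.17 with an estimated correlation). Mesothelial genes were called down (median -3.29, or -2.32 at the bound, adjusted p = 0.036, adjusted p = 0.26 with an estimated correlation). The membrane protein gene Prom2 was at 123 against 11.4 CPM (edgeR adjusted p = 0.039), C3 at 2.66 against 17.5 CPM (adjusted p = 0.039) and the mitochondrial carrier gene Slc25a11 at 123 against 329 CPM (adjusted p = 0.019).

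None of the 6 genes kept its call in every set with 1 library left out: the count was 3 without CGRP replicate 1, 0 without CGRP replicate 3, 1 without CMV replicate 1 and 112 without CMV replicate 3. Prom2 reached an adjusted p of 0.19 without CGRP replicate 3, and C3 and Slc25a11 0.18 without CMV replicate 1. The mesothelial list lost its call without CGRP replicate 2 or 3 or CMV replicate 2 or 3 (highest 0.35).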

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

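The alternatives were chosen before the data were examined, except 3 that were added after seeing the data: leaving out the 5 libraries with counts in fewer than 20000 genes, testing protein coding genes only, and sex as a covariate. AdC minus NE kept a count within 1.5 times of 4008 in every setting but limma voom, and SPC minus CGRP within 1.5 times of 360 except where given below. Of the other pairwise comparisons, FGFR1 minus Mycl and IL minus central moved by over 1.5 times in most settings and the rest in fewer, as given below. The cause was not tested.

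DESeq2 called more genes in each of the 9 pairwise comparisons: 93 for FGFR1 minus control, 412 for Mycl minus control, 870 for FGFR1 minus Mycl, 1188 for SPC minus CGRP, 1219 for junction minus central, 678 for IL minus central, 242 for IL minus junction and 507 for CMV minus CGRP. Limma voom called 4, 19 and 346 in the first 3 of these, 6846 for AdC minus NE, 707 for SPC minus CGRP, 78 for IL minus central and 15 for IL minus junction. For the joint tests DESeq2 was run on only the 3 groups concerned. It called 335 genes for any genotype difference and 992 for any location difference, where edgeR on the same groups called 0 and 312. With only the compared groups in the model, FGFR1 minus Mycl had 9 calls, SPC minus CGRP 617, junction minus central 466, IL minus central 150, IL minus junction 211, CMV minus CGRP 12, any genotype difference 0 (15 with all libraries; 335 by DESeq2) and any location difference 312. Of the genes called with all libraries in the model, 0 of 3 in Mycl minus control, 4 of 62 in FGFR1 minus Mycl, 3470 of 4008 in AdC minus NE, 224 of 360 in SPC minus CGRP, 78 of 106 in junction minus central, 7 of 21 in IL minus central and 1 of 6 in CMV minus CGRP were among these. Library totals in place of TMM gave 26 calls for FGFR1 minus Mycl and 6 for any genotype difference. The median over all genes moved from 0.05 to 0.17 in FGFR1 minus control with library totals. RLE factors moved no count by over 1.5 times, and the 2-fold minimum moved none either.

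Without a filter on low counts there were 1, 14 and 173 calls for FGFR1 minus control, Mycl minus control and FGFR1 minus Mycl, 201, 59 and 2 for junction minus central, IL minus central and IL minus junction, 13 for CMV minus CGRP, 105 for any genotype and 156 for any location difference. The filter at 1 CPM gave 33 for IL minus central. Without the libraries of few genes there were 11 calls for Mycl minus control, 38 for junction minus central (10 shared with the 106), 3 for IL minus central, 11 for CMV minus CGRP and 21 for any location difference. Protein coding genes alone gave 12 for FGFR1 minus Mycl, 33 for IL minus central and 6 for any genotype difference. With sex as a covariate these were 18, 60 and 5, and 86 for any location difference.

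With 1 library left out, edgeR called 0 to 2 genes for FGFR1 minus control, 2 to 10 for Mycl minus control, 6 to 18 for FGFR1 minus Mycl, 3001 to 3403 for AdC minus NE, 140 to 373 for SPC minus CGRP, 34 to 279 for junction minus central, 7 to 185 for IL minus central, 0 to 14 for IL minus junction and 0 to 112 for CMV minus CGRP. Of the genes called, 2244 of 4008 in AdC minus NE, 82 of 360 in SPC minus CGRP, 26 of 106 in junction minus central, 5 of 21 in IL minus central, 2 of 62 in FGFR1 minus Mycl, 1 of 3 in Mycl minus control and 0 of 6 in CMV minus CGRP passed without any 1 library, and all kept their direction. Of 100 list calls 54 did so. The direction of the list test turned for 3 lists, and the cause was not tested. These were mitotic genes in FGFR1 minus control without control replicate 2 (median 0.13, camera adjusted p = 0.84; medians from -0.4 to 0.13), club cell genes in Mycl minus control without control replicate 1 (-0.77, adjusted p = 0.55; from -0.77 to 1.96) and MHC class I genes in CMV minus CGRP without CMV replicate 3 (-0.1, adjusted p = 0.75; from -0.81 to -0.1). Where 1 library of a group was left out, the 2 others shared the spread estimated over all groups.

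The library number as a replicate block gave 207 calls for junction minus central and 71 for IL minus central, against 106 and 21, of which 52 and 4 were shared. It gave 5192 for AdC minus NE, with 3410 of the 4008 shared, and 0 for IL minus junction (edgeR, 1654 at an unadjusted p under 0.05 without the block; DESeq2 242). Deviations from group means of libraries that share a number correlated at -0.016 to 0.096 over 3 CGRP FGFR1 pairs and at -0.011 to 0.12 over 4 CMV Mycl pairs. Low correlations between separate tumours cannot show that they came from different mice. Whether the numbers pair the libraries therefore stays open, and the main model treats the libraries as independent. All 7 pairs with a shared number were of 1 sex, against 3.5 pairs expected by chance, a hint from the data only.

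Of 77 named genes called, 76 kept the call with DESeq2, 73 with RLE factors, 51 of 77 with only the compared groups, and 29 of 46 with the block. Of 129 named genes not called, 10 were called with DESeq2. Of the list calls 95 held with RLE factors, 90 with only the compared groups, 44 of 50 with the block, 36 in fry and 1 with an estimated correlation. With 3 libraries a group and a coefficient of variation of 95%, 29 to 44 of 100 simulated 4-fold changes were recovered. Of the simulated 16-fold changes, 56 to 66 of 100 were. Where as few genes change as in the simulation, most 4-fold changes of single genes would thus be missed. The changed genes were drawn from those with higher counts, and smaller folds were not simulated. In AdC minus NE, 3643 of 4008 called genes changed by at least 2-fold, so some smaller changes were called there.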

Other observations

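Further genes, some of the MYC and FGF receptor families, are given here; they were chosen after their values were seen. Mycn was at 45.9, 40.8 and 27.1 CPM in the 3 AdC libraries from SPC virus and at 1.75, 1.93 and 3.81 CPM in those from CGRP virus (fold change 3.93, SE 1.93, edgeR adjusted p = 0.49). The receptor gene Fgfr2 was between 200 and 313 CPM in the 6 AdC libraries and rose in AdC against NE with CGRP virus and FGFR1 (fold change 2.75, adjusted p = 0.021). Ddx1, the gene next to Mycn, was at 358, 101 and 341 CPM in the NE libraries of that comparison and at 45.5, 55.3 and 49.7 CPM in the AdC libraries (fold change -2.41, adjusted p = 1.4e-05), highest in the 2 NE libraries with high Mycn. Nfib, a transcription factor gene, was at 1246 CPM in central CMV Mycl replicate 3 and at 582 CPM in control replicate 1, and between 84.7 and 354 CPM in the other 22 libraries. Neurod1 was at most 5.49 CPM in any library.

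Of the tests that follow, those on the Mycl and Mycn neighbours, on club cell genes and on pseudogenes without CGRP Mycl replicate 2 were chosen after the result was seen. The test of parent genes of pseudogenes and the counts over other splits of the libraries were planned.

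Mycl or Mycn was high in single NE libraries, and a candidate explanation is a gain in copies, or raised activity, of the whole segment around the gene. Among 14064 windows of the same library, the 10 nearest expressed genes of Mycl lay at percentile 98.9, 99.9 and 99.9 in control replicates 1 and 2 and central CMV Mycl replicate 3, the 3 libraries with Mycl at 4 times its NE median or more. For Mycn this explanation stays open. Its NE median was 0.668 CPM, so 4 times that median is still a low level. Its 10 neighbours lie between positions 9570116 and 15816922, and those of Mycl between 122836242 and 123298925. The Mycn window is thus far wider, and the tests of the 2 genes are not alike. The 5 libraries with Mycn at 4 times its median or more had percentiles of 16.6 (control replicate 1, 5.67 CPM), 52.4 (FGFR1 replicate 2, 2.83 CPM), 77.2 (central CMV Mycl replicate 3, 5.52 CPM), and 97.2 and 99.9 (FGFR1 replicates 1 and 3). A minimum of 10 CPM, tried after these values were seen, would have kept only the last 2 and was dropped. Ddx1 and Nbas, the neighbours nearest to Mycn, were also looked at after their values were seen. On the log2 scale they lay 2.07 and 1.3 above their medians in FGFR1 replicate 1, and 2 and 1.44 in FGFR1 replicate 3. In the other NE libraries they were at most 0.44 and 0.68 above. Reads of an inserted Mycl gene elsewhere in the genome, as the whole source of the high Mycl, are argued against by the neighbours' percentile of 98.9 or more in the 3 libraries, since such reads would raise Mycl alone. No DNA was measured. Wrong labels of control and Mycl libraries stay open: the list of ribosome biogenesis genes, many of them MYC targets, was called up in Mycl as the labels would have it, without any 1 library too, but by a median of 0.26 (adjusted p = 0.36 with an estimated correlation).

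The list of club cell genes was called higher at the junction and at the IL site than centrally (adjusted p = 0.18 and 0.079 with an estimated correlation), and no member passed over all genes at either site. A lower share of tumour cells that raised the markers of every other cell type alike is argued against, with fibroblast genes as the only comparison. The difference between the club cell and fibroblast lists moved by 3.2 at the junction and 4.09 at the IL site on the log2 scale. Central libraries ran from -1.83 to -1.42 and the others from 1.41 to 3.06. A lower share through added airway or alveolar cells need not raise fibroblast genes, so this test cannot argue against it. Markers of some other cell types were higher at the junction with the club cell genes: the mean log2 CPM was 5.13 to 5.7 against 2.31 to 2.55 centrally for alveolar type II genes and 3.86 to 4.26 against 1.98 to 2.73 for endothelial genes, while fibroblast genes were at 2.59 to 3.86 against 2.57 to 4.13. At the IL site ciliated cell genes were at 2.95 to 3.54, against -0.65 to 1.2 centrally. Alveolar type II genes were at 4.29 to 4.31 there, fibroblast genes at 4.02 to 5.21 and endothelial genes at 2.26 to 3.03. Low complexity of the libraries as the whole cause is argued against too. At equal numbers of genes detected the mean log2 CPM of the club cell genes was still 3.18 (SE 0.26) higher at the junction and 4.91 (SE 0.27) at the IL site, against 3.4 and 5.33 without this correction. Central replicate 3, with 26540 genes, had a mean of 2.55, and junction replicate 2, with 18128 genes, one of 4.31. Normal airway and alveolar tissue taken with the tumour, and a change in club cells themselves, stay open and were not tested.

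Pseudogenes made up 36 of the 62 genes called between FGFR1 and Mycl, and their summed level was 2442 to 3119 CPM in the FGFR1 libraries and 7164 to 7288 CPM in the Mycl libraries. In the libraries outside this comparison it was 3946 to 11201 CPM, above every NE FGFR1 library. The pick by calls favours genes low in the NE FGFR1 libraries. Reads shared with parent ribosomal protein genes may account for part of this, since the 10 parent genes had a median fold change of -0.89, against -1.71 for their 14 pseudogenes. Whether low complexity of CGRP Mycl replicate 2 plays a part cannot be decided. Without that library the median of the 36 was -1.41, against -1.47 with it, and 4 of them were still called. The 36 were picked by their calls in this same comparison, so the other libraries largely fix that median. No biological explanation was tested.

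With 3 libraries against 3 there are 10 splits, so the share of splits with as many calls is never under 0.1, which is too few for a share under 0.05. The real split and the highest of the others gave 0 and 8 genes for FGFR1 minus control (10 of 10 splits called as many), 3 and 3 for Mycl minus control (2 of 10), 62 and 1 for FGFR1 minus Mycl (1 of 10), 4008 and 1 for AdC minus NE (1 of 10), 360 and 13 for SPC minus CGRP (1 of 10), 106 and 91 for junction minus central (1 of 10), 21 and 1 for IL minus central (1 of 10), 0 and 0 for IL minus junction (10 of 10), and 6 and 47 for CMV minus CGRP (3 of 10). The split of CMV minus CGRP that called 47 genes does not follow the virus, and why it called more than the real split was not tested. For both counts of 0, the edgeR counts at an unadjusted p under 0.05 were 1080 and 1654, and DESeq2 called 93 and 242. Over 100 splits, the real one included, 1 of 100 called as many genes for any genotype difference (15 genes, highest other 14) in the model of all libraries. For any location difference 2 of 100 did (43 genes, highest other 44). These shares make chance unlikely but do not exclude it, since another split came near the real genotype count and another passed the real location count. The genotype count depends on the model: it was 0 with only the 3 groups in the model and 5 with sex as a covariate, all 3 Mycl libraries being female. DESeq2, also with only the 3 groups, called 335.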
